A study of Rattus norvegicus with 12 samples.

How the data were processed

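RNA from primary astrocyte cultures of the rat optic nerve head was measured on 12 Affymetrix 1-colour arrays, with total RNA as the extracted molecule and biotin as the label per the labels. Group and replicate number were read from the sample titles, since the descriptions of all samples read as control. The groups were EGF and control at 4 h and EGF and control at 12 h, with 3 arrays in each. Whether the replicates were separate cultures is not stated, and they may be technical, in which case the p-values measure only the spread between these samples.

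The deposited values are the intensity of each probe set on a linear scale, made by the authors with MAS5 per the processing notes, with a version not given in the sources used here. The 2% trimmed mean of every array lay between 1500.46 and 1500.56, so the arrays had been scaled to a common mean. They were to be rescaled only if these means differed by over 1.1-fold, and they were not. Median signals ran from 305.5 to 415.2. No detection calls were in the table and none were used. The table held 31099 probe sets, all 12 of its sample columns were used and none were identical. For arrays, the number of arrays limits the precision.

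The 57 control probe sets were left out of the tests. Of the other 31042, the 18625 with a mean signal over the 12 arrays at or above the 40th percentile (215) were tested and 12417 dim ones were left out. The offset of 24.4, the 10th percentile of all signals, was added before taking log2. Group means were fitted with limma 3.58.1 in R 4.3.3 over all 12 arrays, with empirical Bayes moderation and an intensity trend, which left 8 residual degrees of freedom. The contrasts were EGF against control at 4 h and at 12 h, the difference between these effects, and control at 12 h against control at 4 h. All tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. All adjusted p values of genes and lists are from limma. Figures were drawn with matplotlib 3.10.9.

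Probe sets were named from the platform's annotation: 20832 carried 1 symbol, 436 several and 9831 none. Of the named ones, 20764 matched the current gene table by gene identifier and 0 symbols changed. A gene with more than 1 tested probe set, as 2944 of the 10261 genes had, was represented by the probe set with the highest mean signal. List symbols not on the array were resolved through synonyms only when the synonym pointed to 1 measured gene and was not itself a current symbol. No genome build was needed and no coordinates are given.

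The tests, the alternatives, the rule for named genes and 26 gene lists were fixed before the data were examined. The lists covered immediate early factors, feedback inhibitors, EGF family ligands and receptors, G1 and S phase, G2 and mitosis, kinase inhibitors and p53 targets, reactive and mature astrocyte genes, cholesterol and fatty acid synthesis, matrix, proteases, integrins, actin, cytokines, interferon response, growth factors, glycolysis and hypoxia, ribosome biogenesis, and endoplasmic reticulum chaperones, with markers of oligodendrocytes, microglia, neurons, fibroblasts, endothelium and Schwann cells. Each list with at least 5 tested genes was compared with the other genes by limma's camera with a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with the correlation estimated. The list tests were fixed for the 3 comparisons that involve EGF, and those between the controls were added later. Members were also counted with the p-values adjusted over the list alone. The rule named Egfr in every comparison, the 10 largest rises and 10 largest falls at each time among genes past the threshold whose EGF and control arrays did not overlap, the 5 largest differences between times in each direction, and up to 4 members of each list with the smallest p at each time. Named genes are also given in comparisons other than the one that named them.

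Pairing was looked for because both arms of each experiment carry replicate numbers and the cultures were described as sisters. After the group means were taken out, the EGF and control arrays with the same number correlated at 0.121, 0.150 and 0.376 at 4 h. The highest correlation with another number was 0.138, 0.142 and -0.230, so only the replicate 3 pair, which forms a set of arrays of its own, stood clear. The fit with the replicate number within each experiment as a block, which leaves 4 residual degrees of freedom, was among the alternatives.

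Sets of arrays were told apart by time and by their control probe sets. The limits, set after seeing the data, were a mean hybridisation control signal above 1000 and an actin 3' to 5' ratio above 5. A fit with the set as a block and a fit without the replicate 3 pair at 4 h were added for this reason. EGF replicate 3 at 12 h is alone in its set, so the block fit takes the 12 h effects from the other arrays of that time. The alternatives fixed in advance were no offset or one of 96.8 (25th percentile), no filter or one at the 60th percentile (729), quantile normalization, median centring, no intensity trend, array weights, each time alone, 1 probe set per gene, the replicate block, the estimated correlation, the mean over a gene's probe sets, and leaving out each array in turn.

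The procedure was tested on simulated data of the same size with 200 probe sets changed among 18625. A log2 change of 1 was recovered for 37% of them at 4 h and 41% at 12 h, a change of 2 for 89% and 91%, and a change of 0.5 for 0%, with 0 to 8 false calls. In the data themselves 27.8% of the probe sets were called at 4 h and 36.1% at 12 h. With so many calls the adjusted threshold is easier to pass, so the recovered shares do not carry over to the data. At this number of arrays a gene that did not pass may still have changed by 2-fold.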

Results

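Gene expression was measured in primary astrocytes cultured from the rat optic nerve head, the tissue in which the axons of retinal ganglion cells leave the eye. In 1 experiment, cultures given epidermal growth factor (EGF), the ligand of the EGF receptor, for 4 h were set against sister control cultures. In the other, the EGF was given for 12 h, with control cultures of their own. Each of the 4 groups held 3 arrays, 12 in all, each a 1-colour Affymetrix array of 31099 probe sets, and every mean signal is given with its SD over those 3 arrays. After leaving out control probe sets and dim ones, 18625 probe sets were tested, of which 14253 named 1 gene each and 10261 genes in all. Fold changes are given as log2 fold changes with their standard error (SE), on the scale of log2(signal + 24.4). The number of arrays limits the precision, with a median SE of 0.23 for each comparison of EGF with control. The SE of a probe set is pooled over the 4 groups, so it does not measure the spread at 12 h alone. The EGF arrays of 12 h correlated with their own group at a mean r of 0.905 to 0.938, the other arrays at 0.961 to 0.976. Without EGF replicate 3 at 12 h the median SE at 4 h was 0.192. Arrays of the same group correlated at r of 0.899 to 0.979 across the tested probe sets and arrays of different groups at 0.735 to 0.905, where probe sets are not independent replicates.

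Together with the time, the control probe sets of the arrays set 4 sets of arrays apart. By the limits used here, only the time parts EGF replicate 3 at 12 h from replicates 1 and 2 at 4 h. The level of the added transcripts, which the limits do not use, parts them as well. The 3' signal of the added Thr transcript was 6233.5 on EGF replicate 3 at 12 h. It was 48857.9 to 61130.9 on replicates 1 and 2 at 4 h and 2622.8 to 6603.2 on all other arrays. At 4 h, the EGF and the control array of replicate 3 had signals of the bacterial hybridisation control BioD of 21080.5 and 24460.8, against at most 594.8 on the other 10 arrays. At 12 h, the 3 control arrays and EGF replicates 1 and 2 had actin 3' to 5' signal ratios of 11.1 to 21.7, a measure of how far the labelled RNA reaches from its 3' end. EGF replicate 3 at 12 h had a ratio of 1.24, close to the 1.20 to 1.61 of the 4 h arrays. The 3' to 5' ratio of the added Thr transcript was 22.9 to 34.9 on those 5 arrays, 3.87 on EGF replicate 3 at 12 h and 1.76 to 2.58 at 4 h. The sets were found after seeing the data. Counts of probe sets with effects from 1 set, or with the set as a block, are given beside the main ones below.

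**Figure D1:**
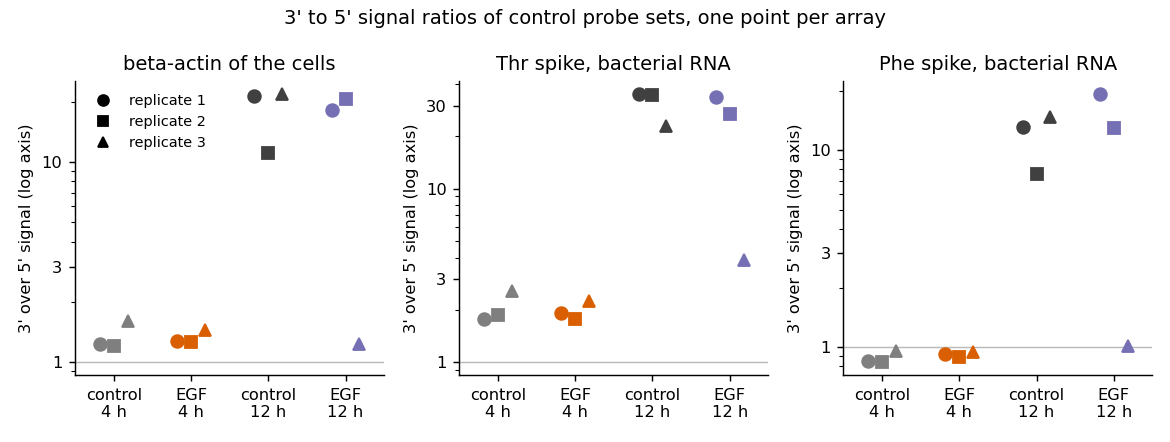
Ratio of the 3' to the 5' signal of control transcripts on each of the 12 arrays, by group, on a log axis. The 5 arrays with actin ratios of 11.1 to 21.7 were the 3 controls and 2 EGF arrays of 12 h, and EGF replicate 3 at 12 h had 1.24.

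After 4 h of EGF, the astrocytes carried far more transcript of the receptor's own ligand Areg (amphiregulin), of the plasminogen activator inhibitor Serpinb2 and of the AP-1 factor Fosl1, and far less of Txnip, which binds thioredoxin. Serpinb2 went from 57.4 ± 28.5 to 23169.7 ± 563 signal units, a log2 fold change of 8.22 ± 0.24 (adjusted p = 4.72e-10). Its control signal lay near background, and with a larger offset of 96.8 the log2 fold change was 7.26. Genes of ribosome biogenesis, feedback inhibitors of receptor signalling, reactive astrocyte genes and cytokine genes rose as groups, the reactive and cytokine lists only in some forms of the test. Txnip fell from 29921 ± 2063 to 2950.1 ± 283 (-3.33 ± 0.13, adjusted p = 2.04e-09). Egfr, the receptor itself, rose from 5578 ± 443 to 8110.4 ± 812 (0.54 ± 0.13, adjusted p = 0.00924).

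Of the tested probe sets, 2118 were higher and 3068 lower with EGF at 4 h at an adjusted p under 0.05, 27.8% of them, and 1051 and 1141 of these changed at least 2-fold. On this scale the naming rule took 10 rises, those of Serpinb2 (8.22 ± 0.24), Areg (6.63 ± 0.23), Tgm1 (5.74 ± 0.35), Nppb (5.63 ± 0.28), Aldh1a3 (5.45 ± 0.47), Arhgap22 (5.28 ± 0.65), C9h6orf141 (5.23 ± 0.21), Fosl1 (5.11 ± 0.22), Fam110c (5.11 ± 0.46) and Gem (4.98 ± 0.36), with adjusted p values up to 4.99e-05. In 5 of these genes the controls lay near background, with a mean under 96.8 (the 25th percentile of all signals) or an array under 24.4. The size and order of such changes depend on the offset, and with an offset of 96.8 the log2 fold change was 7.26 for Serpinb2, 4.57 for Tgm1, 4.23 for Arhgap22, 4.23 for Fam110c and 3.87 for Gem. Nppb encodes the B-type natriuretic peptide, Aldh1a3 an enzyme that makes retinoic acid and Tgm1 a transglutaminase. The 10 falls that the rule took were those of Exph5 (-4.73 ± 0.41), Slc40a1 (-4.33 ± 0.28), Strip2 (-4.10 ± 0.69), Meox2 (-3.74 ± 0.30), Klf15 (-3.61 ± 0.20), Tmcc3 (-3.60 ± 0.25), Atoh8 (-3.52 ± 0.23), Dact1 (-3.52 ± 0.41), Arhgef26 (-3.42 ± 0.36) and Txnip (-3.33 ± 0.13), with adjusted p values up to 6.19e-04. The EGF arrays lay near background in 3 of them, where the offset of 96.8 gave -3.53 for Exph5, -2.81 for Strip2 and -2.60 for Dact1. Slc40a1 is the iron exporter ferroportin, and Meox2, Klf15 and Atoh8 are transcription factors. For all 20 genes the 3 EGF arrays lay on 1 side of the 3 control arrays, which was part of the rule that named them.

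**Figure D2:**
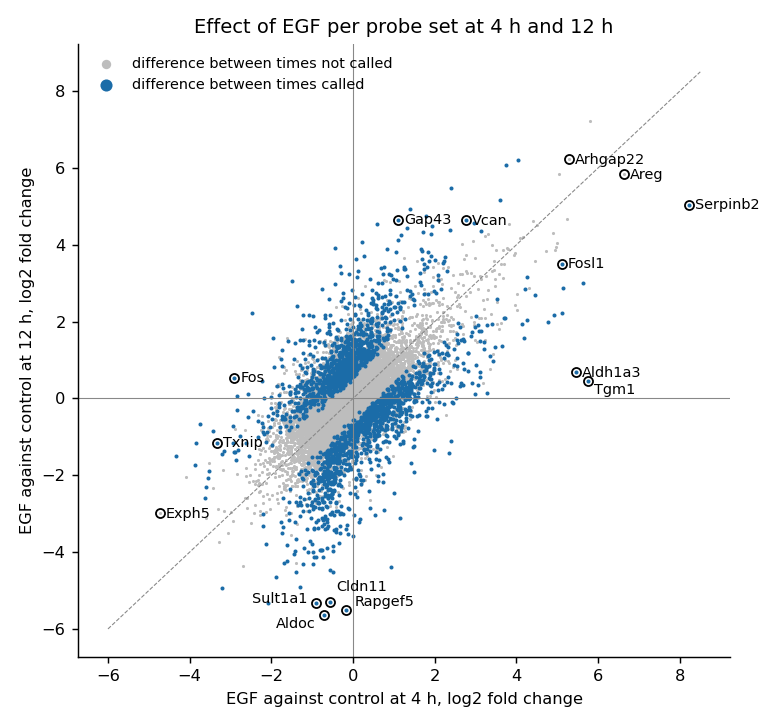
Log2 fold change of EGF against control for each tested probe set at 4 h (horizontal axis) and 12 h (vertical axis), with the probe sets whose effect differed between the times in blue and 15 genes named. The dashed line marks equal effects, and Areg lies near it (6.63 and 5.84) while Tgm1 (5.74 and 0.46) and Rapgef5 (-0.16 and -5.50) lie far from it.

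Among immediate early and AP-1 transcription factors, 13 of 25 measured members rose, 4 fell and 8 passed in neither direction (13 and 4 adjusted over the list alone). Fosl1 and Jun (2.45 ± 0.17), Myc (2.33 ± 0.16) and Egr2 (2.82 ± 0.22) rose, while Fos fell by 2.91 ± 0.19, from 6096 ± 1505 to 776 ± 10.3. Of the feedback inhibitors of receptor tyrosine kinase signalling, 13 of 18 measured members rose, 2 fell and 3 passed in neither direction (14 and 2 adjusted over the list alone). They included the MAP kinase phosphatases Dusp5 (4.72 ± 0.21) and Dusp6 (3.61 ± 0.19) as well as Dusp7 (2.55 ± 0.16) and the receptor inhibitor Errfi1 (3.48 ± 0.20). Of the EGF family ligands and ErbB receptors, 6 of 11 measured members rose, 0 fell and 5 passed in neither direction (6 and 0 adjusted over the list alone). The ligands Areg (6.63 ± 0.23), Hbegf (2.88 ± 0.55) and Ereg (2.06 ± 0.29) were among them. The camera test sets a list against the other genes. The adjusted p of these 3 lists was 1.07e-04, 7.54e-08 and 0.0152. With an estimated correlation it was 0.00949, 0.00854 and 0.0863, so that the first 2 passed. With the set of arrays as a block as well, the immediate early list did not pass (adjusted p = 0.0568).

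Ribosome biogenesis and nucleolus genes moved most evenly. Of them, 27 of 28 measured members rose, 0 fell and 1 passed in neither direction (27 and 0 adjusted over the list alone). Their median log2 fold change was 1.13 (adjusted p = 6.38e-20, and 0.00101 with an estimated correlation). Examples were Odc1 (1.90 ± 0.15), Nop56 (1.85 ± 0.16), Wdr43 (1.62 ± 0.14) and Rrp9 (1.61 ± 0.15), where Odc1 makes the polyamine putrescine. Of the reactive astrocyte genes, 14 of 25 measured members rose, 3 fell and 8 passed in neither direction (14 and 3 adjusted over the list alone). The hyaluronan receptor Cd44 (2.80 ± 0.11), Ptgs2 (4.46 ± 0.22) and Tnc (2.06 ± 0.12) rose. The reactive list had an adjusted p of 4.57e-06, and 0.0165 with an estimated correlation. Of the cytokines, chemokines and NF-kB targets, 13 of 28 measured members rose, 4 fell and 11 passed in neither direction (13 and 4 adjusted over the list alone), with rises in Tnfaip3 (3.10 ± 0.20) and Ccl2 (2.31 ± 0.16). The cytokine list had an adjusted p of 3.25e-05, and 0.00854 with an estimated correlation. Neither the reactive nor the cytokine list passed with an estimated correlation and the set of arrays as a block (adjusted p = 0.0688 for each). Ptgs2, which makes prostaglandins, stands in both lists. Of the extracellular proteases and their inhibitors, 9 of 22 measured members rose, 2 fell and 11 passed in neither direction (9 and 2 adjusted over the list alone). Plaur (3.79 ± 0.42), Serpine2 (3.25 ± 0.22) and Timp1 (1.66 ± 0.18) rose. The protease list had an adjusted p of 0.00728, and 0.0922 with an estimated correlation. Of the glycolysis and hypoxia genes, 8 of 24 measured members rose, 4 fell and 12 passed in neither direction (10 and 6 adjusted over the list alone). The glucose transporter Slc2a1 (1.15 ± 0.14) rose and the peptide hormone Adm (-1.86 ± 0.19) fell. Glycolysis and hypoxia had an adjusted p of 0.0172, and 0.236 with an estimated correlation.

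With the preset correlation, the G1 and S phase list and the G2 and mitosis list were lower at 4 h (adjusted p = 0.0140 and 0.0138). The list of kinase inhibitors and p53 targets (adjusted p = 0.0138) and the interferon list (adjusted p = 0.0109) were lower as well. None of the 4 passed with an estimated correlation, where the adjusted p was 0.298, 0.298, 0.0711 and 0.218. Of the G1 and S phase genes, 1 of 32 measured members rose, 10 fell and 21 passed in neither direction (1 and 11 adjusted over the list alone). Rrm1 (-1.06 ± 0.15), a subunit of ribonucleotide reductase, fell, and Orc6 (0.80 ± 0.19), of the origin recognition complex, rose. Of the G2 and mitosis genes, 0 of 26 measured members rose, 9 fell and 17 passed in neither direction (0 and 10 adjusted over the list alone). Ect2 (-1.38 ± 0.26) and Kif11 (-1.07 ± 0.23) were among the lower. Of the cyclin dependent kinase inhibitors and p53 targets, 1 of 16 measured members rose, 9 fell and 6 passed in neither direction (1 and 11 adjusted over the list alone). Ccng2 (-3.20 ± 0.14), Gadd45b (-2.30 ± 0.15) and Cdkn1b (-1.38 ± 0.13) fell, of which Cdkn1b holds cells in G1. Of the interferon response genes, 0 of 24 measured members rose, 9 fell and 15 passed in neither direction (0 and 9 adjusted over the list alone). Irf1 (-1.73 ± 0.17) and Irf9 (-1.04 ± 0.13) fell. Under median centring and quantile normalization the members of G2 and mitosis that fell numbered 3, and under median centring those of G1 and S phase numbered 6. They numbered 13 and 20 with the set of arrays as a block, and without EGF replicate 3 at 12 h, which enters the spread, 12 and 13.

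Of the other lists at 4 h, none passed. Cholesterol synthesis and uptake had 6 higher and 3 lower of 20 (6 and 4 adjusted over the list alone; adjusted p = 0.0604), with Msmo1 (2.62 ± 0.19) and Hsd17b7 (2.03 ± 0.14) among the higher members. That list passed in the fit that pairs the arrays by replicate number (adjusted p = 0.0368, range over alternatives 0.0199 to 0.293). It also passed with the set of arrays as a block (adjusted p = 0.0287) and without EGF replicate 3 at 12 h (0.0465). In these last fits it did not pass with an estimated correlation (adjusted p = 0.370 and 0.334). Integrins and cell adhesion had 9 higher and 5 lower of 22 (9 and 8 adjusted over the list alone; adjusted p = 0.0664). Collagens and other extracellular matrix had 9 higher and 4 lower of 45 (9 and 4 adjusted over the list alone; adjusted p = 0.145). The actin cytoskeleton list had 8 higher and 5 lower of 38 (8 and 5 adjusted over the list alone; adjusted p = 0.230). Fatty acid synthesis had 3 higher and 1 lower of 14 (3 and 1 adjusted over the list alone; adjusted p = 0.519). Secreted growth and neurotrophic factors had 8 higher and 7 lower of 31 (8 and 7 adjusted over the list alone; adjusted p = 0.230). Among those factors, Inhba (3.45 ± 0.19) and Fgf2 (2.54 ± 0.22) rose and Bmp4 (-1.51 ± 0.12) fell. The endoplasmic reticulum chaperones had 2 higher and 6 lower of 25 (2 and 6 adjusted over the list alone; adjusted p = 0.705). Mature astrocyte genes had 0 higher and 4 lower of 19 (0 and 2 adjusted over the list alone; adjusted p = 0.230). For integrins, collagens, the actin list, fatty acid synthesis and growth factors the median log2 fold change was below 0 (-0.04, -0.17, -0.03, -0.03 and -0.23) while the test pointed up.

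Markers of other cell types were counted in the same way. Oligodendrocyte lineage markers had 0 higher and 4 lower of 7 (1 and 4 adjusted over the list alone; adjusted p = 0.230). Fibroblast and meningeal markers had 3 higher and 2 lower of 22 (3 and 1 adjusted over the list alone; adjusted p = 0.925). Endothelial and pericyte markers had 1 higher and 1 lower of 8 (2 and 1 adjusted over the list alone; adjusted p = 0.758). Schwann cell markers had 2 higher and 0 lower of 5 (2 and 0 adjusted over the list alone; adjusted p = 0.112). The 2 were Egr2, also in the immediate early list, and Gap43, also in the neuron list. Prx and Pmp22 did not pass (adjusted p = 0.146 and 0.330). Neuron markers had 1 higher and 0 lower of 6 (1 and 0 adjusted over the list alone; adjusted p = 0.339). Microglia and macrophage markers had 0 higher and 0 lower of 7 (0 and 0 adjusted over the list alone; adjusted p = 0.886). The microglia and endothelial lists had medians of -0.05 and -0.27 while the test pointed up.

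The median log2 fold change of all tested probe sets at 4 h was -0.15, and centring each array on its median moved it to 0.05, changed the lower calls to 1509 and the share of higher calls from 40.8% to 63.8%. With the set of arrays as a block, 3103 probe sets were higher and 4960 lower. Without the replicate 3 pair at 4 h the counts were 1669 and 2109, with effects from the 4 arrays of replicates 1 and 2. The spread in that fit was still pooled with the 12 h arrays. In the replicate 3 pair alone, which has no replicate, the log2 ratios correlated at r = 0.777 with those of replicates 1 and 2 across the tested probe sets.

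After 12 h of EGF, Areg and Serpinb2 were still far above control, and sterol synthesis genes were higher as a group. Glycolysis and actin cytoskeleton genes were higher and mitosis genes lower as groups with the preset correlation, but not with an estimated one (adjusted p = 0.118, 0.192 and 0.169). Cldn11, a tight junction protein of myelin and other sheaths, fell from 45897 ± 1891 to 1146 ± 146 signal units (-5.30 ± 0.12, adjusted p = 2.34e-11). Areg rose from 67.0 ± 19.1 to 5266 ± 1376 (5.84 ± 0.23, adjusted p = 1.54e-09). The sulfotransferase Sult1a1 (-5.34 ± 0.13) and the aldolase Aldoc (-5.64 ± 0.64), an astrocyte enzyme, fell as well. Egfr was lower, from 7995 ± 609.8 to 5646 ± 809.9 (-0.51 ± 0.13, adjusted p = 0.00978), and did not pass under median centring (adjusted p = 0.0612, the highest of 25 alternatives, whose lowest was 3.14e-04).

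At 12 h, 2848 probe sets were higher and 3882 lower, 36.1% of those tested, with 1399 and 1831 changed at least 2-fold. The 10 rises that the rule took were those of Arhgap22 (6.23 ± 0.65), Akr1c3 (6.21 ± 0.45), Areg (5.84 ± 0.23), Cyp3a9 (5.47 ± 0.43), Akr1b8 (5.16 ± 0.17), Serpinb2 (5.04 ± 0.24), Ptprn (4.75 ± 0.38), C9h6orf141 (4.68 ± 0.21), Gap43 (4.65 ± 0.33) and Vcan (4.64 ± 0.20), with adjusted p values up to 7.85e-06. Controls lay near background in 2 of them, where the offset of 96.8 gave 5.38 for Arhgap22 and 5.005 for Areg. Akr1c3 and Akr1b8 are aldo-keto reductases, Gap43 is a growth cone protein and Vcan is the matrix proteoglycan versican. The rule's 10 falls were those of Aldoc (-5.64 ± 0.64), Rapgef5 (-5.50 ± 0.25), Sult1a1 (-5.34 ± 0.13), Lrtm2 (-5.33 ± 0.36), Cldn11 (-5.30 ± 0.12), Dhrs3 (-4.93 ± 0.19), Angpt2 (-4.90 ± 0.23), Adh1c (-4.64 ± 0.40), Dmrtc1a (-4.51 ± 0.31) and Adam22 (-4.48 ± 0.33), with adjusted p values up to 1.81e-05. In 4 of these the EGF arrays lay near background, and the offset of 96.8 gave -4.43 for Aldoc, -4.22 for Lrtm2, -3.94 for Adh1c and -3.49 for Dmrtc1a. Dhrs3 and Adh1c are oxidoreductases of retinoids and alcohols, and Angpt2 is an angiopoietin. As at 4 h, the EGF and control arrays of these 20 genes did not overlap.

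**Figure D3:**
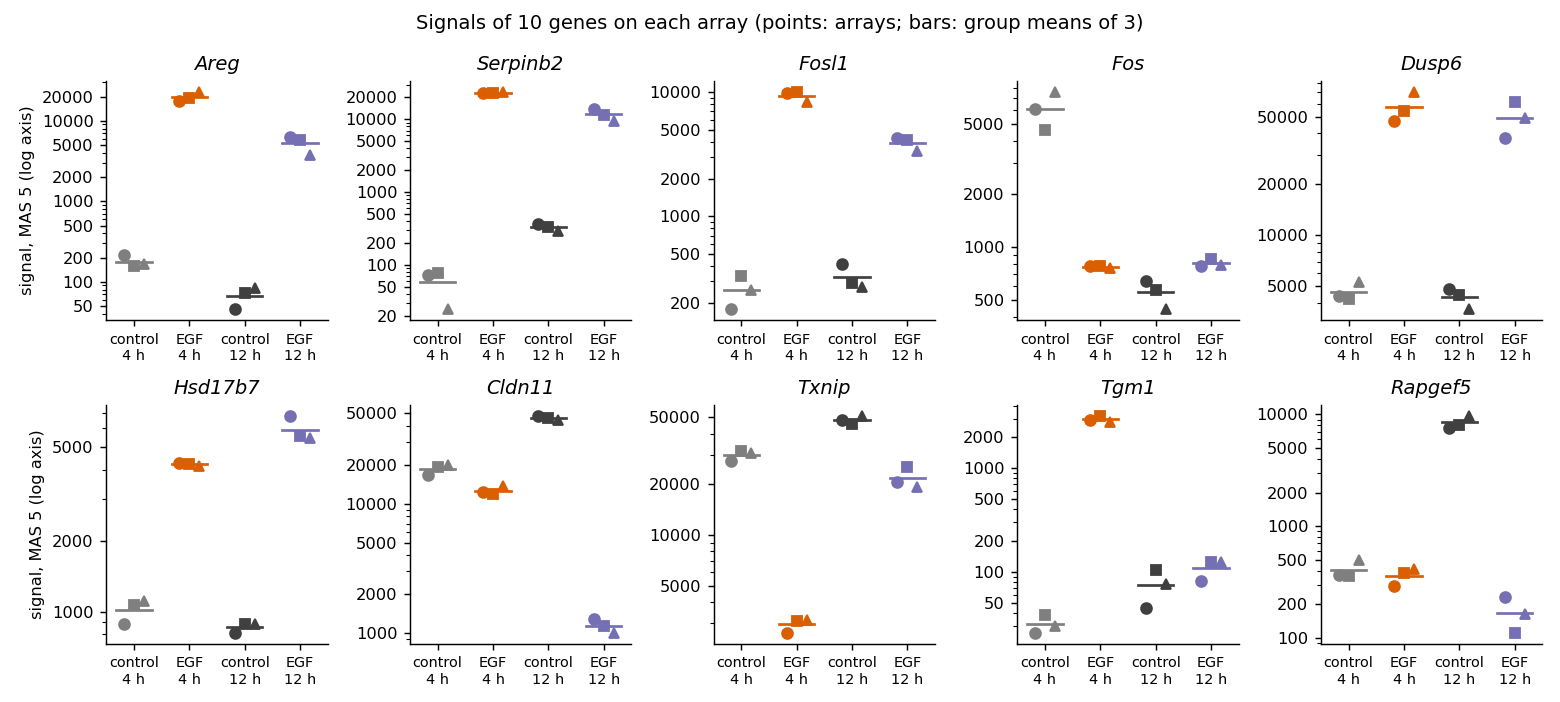
Signal of 10 genes on each array, on log axes, with points for arrays and bars for the means of 3. Areg and Serpinb2 were higher in every EGF array than in every control array of the same time, and Cldn11 fell from 45897 to 1146 at 12 h.

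The immediate early list held 13 members of 25 that rose and 0 that fell (13 and 1 adjusted over the list alone), with Fosl1 (3.51 ± 0.22), Jun (2.07 ± 0.17), Klf6 (1.79 ± 0.13) and Egr1 (1.55 ± 0.13) as examples. Fos was 553 ± 101 in controls and 807 ± 38.7 with EGF (0.54 ± 0.19, adjusted p = 0.0442). Of the feedback inhibitors, 13 of 18 measured members rose, 1 fell and 4 passed in neither direction (13 and 1 adjusted over the list alone). Dusp5 (3.84 ± 0.21) and Dusp6 (3.50 ± 0.19) rose. The adjusted p of these 2 lists was 7.61e-07 and 1.51e-06, and 0.00878 and 0.0132 with an estimated correlation. Of the reactive astrocyte genes, 13 of 25 measured members rose, 6 fell and 6 passed in neither direction (14 and 6 adjusted over the list alone). The galectin Lgals3 (3.57 ± 0.15), Cd44 (3.26 ± 0.11) and Cxcl10 (3.89 ± 0.26) were higher and Tm4sf1 (-1.63 ± 0.13) lower. The reactive list had an adjusted p of 0.00214, and 0.0970 with an estimated correlation.

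Cholesterol synthesis and uptake genes rose together. Of them, 15 of 20 measured members rose, 0 fell and 5 passed in neither direction (17 and 0 adjusted over the list alone). Their median log2 fold change was 1.29 (adjusted p = 1.25e-09, and 0.0106 with an estimated correlation). With the set of arrays as a block too, the latter became 0.0616 and did not pass. The enzymes Hsd17b7 (2.74 ± 0.14), Msmo1 (2.37 ± 0.19) and Fdps (2.22 ± 0.14) and the sterol sensor partner Insig1 (1.92 ± 0.18) rose. Of the fatty acid synthesis genes, 6 of 14 measured members rose, 0 fell and 8 passed in neither direction (6 and 0 adjusted over the list alone). Elovl6 (1.62 ± 0.21) and Fasn (1.06 ± 0.14) rose. Fatty acid synthesis had an adjusted p of 0.00535, and 0.158 with an estimated correlation. Of the glycolysis and hypoxia genes, 14 of 24 measured members rose, 5 fell and 5 passed in neither direction (15 and 5 adjusted over the list alone). Pfkp (2.56 ± 0.15), Ldha (2.20 ± 0.14) and Eno1 (1.91 ± 0.15) rose. Glycolysis had an adjusted p of 9.22e-04, and 0.118 with an estimated correlation. Of the ribosome biogenesis genes, 20 of 28 measured members rose, 0 fell and 8 passed in neither direction (21 and 0 adjusted over the list alone). Fbl (1.22 ± 0.14) and Nop58 (1.15 ± 0.16) rose. Ribosome biogenesis had an adjusted p of 5.14e-08, and 0.0106 with an estimated correlation. Of the endoplasmic reticulum chaperones and unfolded protein response genes, 12 of 25 measured members rose, 2 fell and 11 passed in neither direction (12 and 2 adjusted over the list alone). Atf4 (1.65 ± 0.18) and Xbp1 (0.74 ± 0.12) rose and Herpud1 (-1.36 ± 0.22), a target of that response, fell. The chaperone list had an adjusted p of 0.00112, and 0.0198 with an estimated correlation. The latter became 0.0685 with the set of arrays as a block. Of the actin cytoskeleton and motility genes, 17 of 38 measured members rose, 8 fell and 13 passed in neither direction (17 and 8 adjusted over the list alone). Msn (2.37 ± 0.14) and Actn1 (2.33 ± 0.15) rose and the myosin light chain Myl9 (-2.23 ± 0.15) fell. The actin list had an adjusted p of 0.00238, and 0.192 with an estimated correlation.

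Of the G2 and mitosis genes at 12 h, 0 of 26 measured members rose, 19 fell and 7 passed in neither direction (1 and 20 adjusted over the list alone). Nusap1 (-1.97 ± 0.20), Ect2 (-2.27 ± 0.26) and Ccnb2 (-1.27 ± 0.21) fell, and the median of the list was -1.02 (adjusted p = 5.71e-04, and 0.169 with an estimated correlation). Of the interferon response genes, 0 of 24 measured members rose, 10 fell and 14 passed in neither direction (0 and 11 adjusted over the list alone). Rtp4 (-3.24 ± 0.50) and Mx2 (-1.90 ± 0.19) fell. The interferon list had an adjusted p of 0.0121, and 0.169 with an estimated correlation. Lower members of both lists and higher members of the sterol list were measured on arrays of which 5 of 6 had skewed 3' to 5' ratios.

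**Figure D4:**
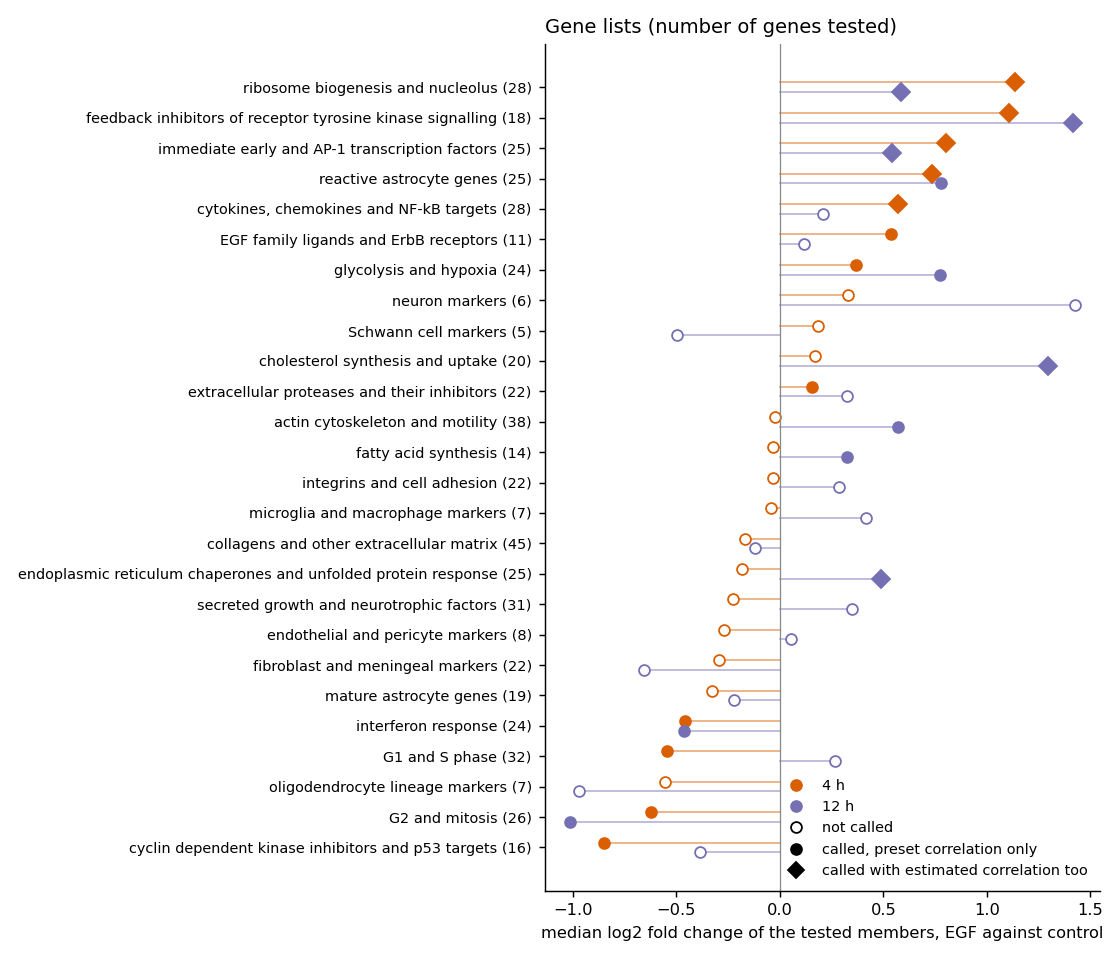
Median log2 fold change of the tested members of each of the 26 gene lists at 4 h and 12 h, with the number of genes tested, filled circles for lists called with the preset correlation only and diamonds for lists called with an estimated one too. Ribosome biogenesis had the highest median at 4 h among the lists called (1.13), and cholesterol synthesis had a median of 0.17 at 4 h and 1.29 at 12 h.

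The remaining lists did not pass at 12 h. G1 and S phase had 4 higher and 2 lower of 32 (4 and 2 adjusted over the list alone; adjusted p = 0.0777), with cyclin D1 (Ccnd1, 1.18 ± 0.19) higher and Rrm1 (-1.74 ± 0.15) lower. The CDK inhibitor list had 3 higher and 8 lower of 16 (3 and 8 adjusted over the list alone; adjusted p = 0.155). The EGF family list had 3 higher and 2 lower of 11 (3 and 2 adjusted over the list alone; adjusted p = 0.289). Proteases had 10 higher and 6 lower of 22 (10 and 8 adjusted over the list alone; adjusted p = 0.0738). Integrins and cell adhesion had 11 higher and 7 lower of 22 (11 and 7 adjusted over the list alone; adjusted p = 0.0777). Of these, Sdc1 (3.99 ± 0.13) and Cdh1 (-2.50 ± 0.18) went opposite ways. Collagens and other matrix had 10 higher and 16 lower of 45 (13 and 18 adjusted over the list alone; adjusted p = 0.817). In it Nid2 (2.72 ± 0.16) was higher and decorin (Dcn, -3.03 ± 0.16) lower, and the list's mean was above 0 while its median and test pointed down. Cytokines had 9 higher and 8 lower of 28 (9 and 8 adjusted over the list alone; adjusted p = 0.328), with Cxcl12 at -2.85 ± 0.17. Growth factors had 8 higher and 10 lower of 31 (10 and 10 adjusted over the list alone; adjusted p = 0.810), with a mean of -0.01 against a median of 0.35. Without EGF replicate 3 that median was -0.19, so its sign rests on that array. The mature astrocyte genes had 1 higher and 6 lower of 19 (1 and 6 adjusted over the list alone; adjusted p = 0.0783). The glutamine synthetase Glul (-1.28 ± 0.15), the bicarbonate transporter Slc4a4 (-2.25 ± 0.12) and Aldoc were lower. As a list these genes passed without EGF replicate 3 (adjusted p = 0.0479, range over alternatives 0.0114 to 0.187), but not with an estimated correlation as well (adjusted p = 0.174).

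Of the marker lists at 12 h, fibroblast and meningeal markers had 3 higher and 12 lower of 22 (3 and 12 adjusted over the list alone; adjusted p = 0.0563), with Dcn lower and S100a4 higher (3.10 ± 0.16). Oligodendrocyte lineage markers had 1 higher and 4 lower of 7 (1 and 4 adjusted over the list alone; adjusted p = 0.0655), with Cldn11 among the lower. Without EGF replicate 3 both passed (adjusted p = 0.0103 and 0.0448, and 0.116 and 0.133 with an estimated correlation). Over all alternatives the adjusted p ranged from 0.0103 to 0.169 for fibroblast markers and from 0.00294 to 0.335 for oligodendrocyte markers. Neuron markers had 3 higher and 0 lower of 6 (3 and 0 adjusted over the list alone; adjusted p = 0.0563), with Gap43 (4.65 ± 0.33) and Slc17a6 (3.10 ± 0.57) higher. The adjusted p of that list ranged from 0.0222 to 0.158 over the alternatives. Microglia and macrophage markers had 1 higher and 0 lower of 7 (1 and 0 adjusted over the list alone; adjusted p = 0.163). Among them Cd68, a lysosomal protein, rose from 62.1 ± 62.5 to 924 ± 114. Endothelial and pericyte markers had 2 higher and 2 lower of 8 (2 and 2 adjusted over the list alone; adjusted p = 0.688). Schwann cell markers had 2 higher and 2 lower of 5 (2 and 2 adjusted over the list alone; adjusted p = 0.597), with a median of -0.50 while the test pointed up.

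Without EGF replicate 3, 2930 probe sets were higher and 3881 lower at 12 h, and 2458 and 3323 of these were also called with all arrays. The effects then come from the 5 arrays with skewed ratios, while the spread is still pooled with the 4 h arrays. With the set of arrays as a block the counts were 3444 and 4500. With all arrays, the 12 h fold changes include EGF replicate 3, whose set is not that of the controls. EGF replicate 3 is the only array of its set, so the block takes it out of the 12 h effects. The 12 h fold changes of that fit are those without EGF replicate 3, and only the spread differs.

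The effect of EGF differed between 12 h and 4 h for 2153 probe sets, 1015 with a higher and 1138 with a lower log2 fold change at 12 h, 11.6% of those tested. Tgm1, 2963 ± 215 with EGF at 4 h, was 110.2 ± 25.2 with EGF at 12 h, and the difference of the effects was -5.28 ± 0.50 (adjusted p = 3.52e-05). Sterol synthesis and chaperone genes had higher effects at 12 h, and ribosome biogenesis genes lower ones, in calls that depend on the form of the test. Fos, lower with EGF at 4 h, had a difference of 3.45 ± 0.28 (adjusted p = 9.58e-06), with controls at 6096 ± 1505 at 4 h and 553 ± 101 at 12 h. For Egfr, higher at 4 h and lower at 12 h, the difference was -1.04 ± 0.19 (adjusted p = 0.00375).

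The 5 differences upward that the rule took were those of Gdf6 (4.68 ± 0.92), Emb (3.96 ± 0.28), Plcd4 (3.84 ± 0.65), Ifi27l2b (3.57 ± 0.30) and Gap43 (3.56 ± 0.46), with adjusted p values up to 0.00574. The 5 downward were those of Rapgef5 (-5.34 ± 0.35), Gjb6 (-5.33 ± 0.98), Tgm1 (-5.28 ± 0.50), Aldoc (-4.93 ± 0.91) and Aldh1a3 (-4.77 ± 0.67), with adjusted p values up to 0.00402, where Gjb6 is the astrocyte gap junction protein connexin 30. At least 1 group lay near background in 2 of the former, where the offset of 96.8 gave 3.64 for Gdf6 and 3.25 for Plcd4, and in 3 of the latter, where it gave -3.65 for Gjb6, -4.30 for Tgm1 and -3.97 for Aldoc. For several of these genes the controls differed as well, and the controls enter the difference with the opposite sign. The Rapgef5 signal was 406 ± 77.2 in the 4 h controls, 360.2 ± 64.1 with EGF at 4 h, 8485 ± 1131 in the 12 h controls and 169 ± 60.1 with EGF at 12 h. Between the controls at 12 h and 4 h, the log2 fold change was 4.31 ± 0.25 for Rapgef5, 4.18 ± 0.64 for Aldoc, 4.79 ± 0.69 for Gjb6, -4.49 ± 0.65 for Gdf6 and -4.60 ± 0.21 for Ifi27l2b. Gjb6 in the 4 h and Gdf6 in the 12 h controls lay near background, and the offset of 96.8 gave 3.41 and -3.39. For Tgm1 it was 0.80 ± 0.35 (adjusted p = 0.0818) and for Plcd4 1.01 ± 0.46 (adjusted p = 0.0883), which did not pass, and both lay near background in the 4 h controls.

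Across lists, the effect was higher at 12 h for cholesterol synthesis and uptake, with 12 higher and 0 lower of 20 (14 and 0 adjusted over the list alone; adjusted p = 4.16e-08). So it was for the endoplasmic reticulum chaperones, with 8 higher and 0 lower of 25 (9 and 1 adjusted over the list alone; adjusted p = 6.34e-05). Between the controls the chaperones moved the other way, with 1 higher and 12 lower at 12 h than at 4 h (adjusted p = 9.01e-05, and 0.0112 with an estimated correlation). The effect of EGF was lower at 12 h for ribosome biogenesis, with 0 higher and 9 lower of 28 (1 and 12 adjusted over the list alone; adjusted p = 5.42e-05). These 3 also passed with an estimated correlation (adjusted p = 0.0268, 0.0268 and 0.0392). With the set of arrays as a block none of the 3 passed that test (adjusted p = 0.125, 0.0666 and 0.0666). Without EGF replicate 3 at 12 h the cholesterol and ribosome lists did not pass it (0.0560 for each). With the preset correlation only, upward differences were also called for 4 more lists, G1 and S phase, fatty acid synthesis, actin and glycolysis. With an estimated correlation their adjusted p was 0.182, 0.182, 0.314 and 0.278. The G1 and S phase list had 7 higher and 0 lower of 32 (14 and 1 adjusted over the list alone; adjusted p = 5.42e-05). These numbered 11 and 1 without EGF replicate 3 at 12 h, and 14 and 1 with the set of arrays as a block. Fatty acid synthesis had 3 higher and 0 lower of 14 (5 and 0 adjusted over the list alone; adjusted p = 0.00891). The actin list had 8 higher and 5 lower of 38 (12 and 5 adjusted over the list alone; adjusted p = 0.0182). Glycolysis had 9 higher and 3 lower of 24 (10 and 4 adjusted over the list alone; adjusted p = 0.0467). Cytokines went down, with 1 higher and 10 lower of 28 (2 and 10 adjusted over the list alone; adjusted p = 0.00891), and fibroblast markers too, with 1 higher and 6 lower of 22 (1 and 7 adjusted over the list alone; adjusted p = 0.0174). Neither passed with an estimated correlation (adjusted p = 0.0527 and 0.182). The median of the cytokine list was -0.04, and it turned to 0.01 under quantile normalization while the test still pointed down. Tnfaip3 (-2.42 ± 0.28) and Ccl2 (-1.87 ± 0.23) had lower effects at 12 h and Cxcl10 (2.22 ± 0.36) a higher one. Without EGF replicate 3 at 12 h, the actin and glycolysis lists did not pass (adjusted p = 0.0646 and 0.104). Over all alternatives their adjusted p ranged from 0.00599 to 0.314 and from 0.0170 to 0.278. The actin list also did not pass without control replicate 3 at 12 h (adjusted p = 0.0908), nor the fibroblast list without EGF replicate 1 at 12 h (adjusted p = 0.0748, range 0.00176 to 0.182).

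The control arrays enter the difference of the effects and the comparison of the controls alike, with opposite signs. Of the 9 lists with a difference, 4 were also called between the controls, all lower at 12 h, and chaperones and the actin list were 2 of them. The actin list had 3 higher and 21 lower of 38 (adjusted p = 1.09e-09, and 0.0413 with an estimated correlation). Cytokines, whose difference was downward, had 4 higher and 14 lower of 28 (3.74e-05 and 0.0112). Fibroblast markers had 4 and 7 of 22 (0.0444, and 0.186, which does not pass). For cholesterol synthesis, ribosome biogenesis, G1 and S phase, fatty acid synthesis and glycolysis the adjusted p between the controls was 0.239, 0.0867, 0.130, 0.896 and 0.170.

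No difference was called for the other 17 lists. The immediate early list had 6 higher and 4 lower of 25 (7 and 5 adjusted over the list alone; adjusted p = 0.264). Feedback inhibitors had 2 higher and 3 lower of 18 (3 and 5 adjusted over the list alone; adjusted p = 0.574). The EGF family had 0 higher and 3 lower of 11 (2 and 3 adjusted over the list alone; adjusted p = 0.181). G2 and mitosis had 0 higher and 1 lower of 26 (0 and 1 adjusted over the list alone; adjusted p = 0.120). CDK inhibitors had 2 higher and 0 lower of 16 (3 and 1 adjusted over the list alone; adjusted p = 0.147). Reactive astrocyte genes had 3 higher and 6 lower of 25 (4 and 7 adjusted over the list alone; adjusted p = 0.490). Mature astrocyte genes had 0 higher and 4 lower of 19 (0 and 4 adjusted over the list alone; adjusted p = 0.344). Collagens had 4 higher and 9 lower of 45 (4 and 11 adjusted over the list alone; adjusted p = 0.140). Proteases had 2 higher and 2 lower of 22 (2 and 3 adjusted over the list alone; adjusted p = 0.326). Integrins had 2 higher and 3 lower of 22 (7 and 4 adjusted over the list alone; adjusted p = 0.698). Without EGF replicate 3 at 12 h the integrins had 6 and 4, and 7 and 5 with the set of arrays as a block. Interferon genes had 1 higher and 2 lower of 24 (1 and 2 adjusted over the list alone; adjusted p = 0.833). Growth factors had 3 higher and 6 lower of 31 (3 and 7 adjusted over the list alone; adjusted p = 0.120). Oligodendrocyte markers had 0 higher and 1 lower of 7 (0 and 1 adjusted over the list alone; adjusted p = 0.181). Microglia markers had 1 higher and 0 lower of 7 (1 and 0 adjusted over the list alone; adjusted p = 0.186). Neuron markers had 2 higher and 0 lower of 6 (2 and 0 adjusted over the list alone; adjusted p = 0.120). Endothelial markers had 0 higher and 0 lower of 8 (0 and 0 adjusted over the list alone; adjusted p = 0.977). Schwann cell markers had 1 higher and 2 lower of 5 (1 and 2 adjusted over the list alone; adjusted p = 0.359). The mean of the feedback, mature astrocyte, integrin and Schwann lists had another sign than the median or lay at 0.

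The effects at the 2 times were related. Across the 18625 tested probe sets the log2 fold changes at 4 h and 12 h correlated at r = 0.588 (Spearman's rho 0.538), where probe sets are not independent replicates, and the controls of the 2 times were separate arrays. Probe sets higher at both times numbered 1170, where independent lists of those sizes would share 324, and those lower at both numbered 1827, against 639. In opposite directions, 89 were higher at 4 h and lower at 12 h, and 64 the reverse. Without EGF replicate 3 at 12 h, 1501 probe sets had a higher and 1454 a lower difference, and 985 and 1123 of these were among those called with all arrays. With the set of arrays as a block the counts were 2168 and 1924, and under median centring the share of higher differences went from 47.1% to 33.5%, with 562 higher.

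The control arrays themselves differed between the experiments. Rapgef5, Gjb6 and Aldoc were higher in the 12 h than in the 4 h controls and Fos was lower (-3.39 ± 0.19, adjusted p = 1.77e-07), as was Ccl2 (-2.13 ± 0.16). Egfr was 0.52 ± 0.13 higher (adjusted p = 0.00747). By list, 10 of the 26 were called, all lower at 12 h, and 6 of them also with an estimated correlation, against 5 for EGF at either time. These list tests were not among those fixed in advance, which covered the other 3 comparisons. The interferon list had 0 higher and 16 lower of 24 (adjusted p = 1.09e-09, and 0.0137 with an estimated correlation). Growth factors had 3 and 15 of 31 (1.15e-04 and 0.0112), and immediate early genes 6 and 11 of 25 (0.00218 and 0.0245). The chaperone, actin and cytokine lists were the other 3. These 6 passed in all 24 alternatives. The EGF family, reactive astrocyte, collagen and fibroblast lists passed only with the preset correlation (adjusted p = 0.0353, 0.0353, 0.00918 and 0.0444, and 0.122, 0.186, 0.186 and 0.186 with an estimated one). In all, 8458 probe sets differed, 4425 higher and 4033 lower at 12 h, more than between EGF and control at either time. In that comparison 465 genes had probe sets called in both directions, against 3 and 28 in the comparisons of EGF with control at 4 h and 12 h. Since the controls of the 2 times lay in different sets of arrays, time and set cannot be told apart in this comparison. Median centring changed the share of higher calls from 52.3% to 63.4% and the median log2 fold change from 0.08 to 0.25.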

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

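The tests of the labelling reaction, of RNA degraded before the added transcripts, of replicate 3 alone and of the number of lists between the controls were chosen only after the results they measure were seen.

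The effect of EGF differed between the times by limma's test of the difference, with 1015 probe sets higher and 1138 lower at 12 h than at 4 h. Of the 1015, 474 were called at 4 h and 759 at 12 h, and of the 1138, 696 and 824. By gene the log2 difference was 4.68 for Gdf6, 3.96 for Emb, 3.84 for Plcd4, 3.57 for Ifi27l2b and 3.56 for Gap43, and -5.34 for Rapgef5, -5.33 for Gjb6, -5.28 for Tgm1, -4.93 for Aldoc and -4.77 for Aldh1a3. Where a group lay near background the size depends on the offset. The controls enter these differences with the opposite sign. Between the controls at 12 h and 4 h, the log2 fold change was -4.49 for Gdf6 and -4.60 for Ifi27l2b. It was 4.31 for Rapgef5, 4.79 for Gjb6 and 4.18 for Aldoc. For these genes a change in the effect of EGF cannot be told from this shift between the controls. The shift was -1.53 for Emb, 1.01 for Plcd4, 1.25 for Gap43, 0.80 for Tgm1 and 1.24 for Aldh1a3. By list the adjusted p of the difference was 5.42e-05 for G1 and S phase, 4.16e-08 for cholesterol synthesis, 0.00891 for fatty acid synthesis, 0.0182 for the actin cytoskeleton, 0.00891 for cytokines, 0.0467 for glycolysis, 5.42e-05 for ribosome biogenesis, 6.34e-05 for endoplasmic reticulum chaperones and 0.0174 for fibroblast markers. Of these 9 lists only cholesterol synthesis, chaperones and ribosome biogenesis passed with an estimated correlation, where the adjusted p of the other 6 was 0.182, 0.182, 0.314, 0.0527, 0.278 and 0.182, in the order given. None of the 3 passed that test with the set of arrays as a block (adjusted p = 0.125, 0.0666 and 0.0666). Chaperones, the actin list, cytokines and fibroblast markers were also lower as lists in the 12 h than in the 4 h controls (adjusted p = 9.01e-05, 1.09e-09, 3.74e-05 and 0.0444, and 0.0112, 0.0413, 0.0112 and 0.186 with an estimated correlation).

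Of 100 splits of the samples within each time, drawn with the real one included, 4 gave at least the real 2153 probe sets with a difference, and the highest of the other splits gave 8082. These splits mix EGF and control, so they test whether EGF had any effect and not whether its effects were equal at the 2 times. The 80 that mixed both times gave 0 by limma. The 8 that kept the groups whole at 12 h and mixed them at 4 h gave 693 to 2525. The 10 that kept them whole at 4 h and mixed them at 12 h gave 45 to 1121. The split with 8082 exchanged EGF and control at 12 h. For the number of lists with a difference, 30 splits gave at least the real 9, and the highest other gave 14. With an estimated correlation the real number was 3 and the highest other 6, in 2 splits with at least 3. For the difference between the times these splits say nothing about chance.

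Weaker signals at 12 h would shrink every effect, but 36.7% of the called probe sets had a smaller change at 12 h. Without replicate 3 of EGF at 12 h, 97.9% of the called probe sets were called the same way. The median SE of the difference also went from 0.326 to 0.288 without that array. Calls made despite the wider spread would mostly stay, so the share kept cannot tell how much that array adds. A difference was still called without it, for 1501 probe sets higher and 1454 lower at 12 h, so the difference does not rest on that array alone. The 12 h arrays differ from the 4 h arrays in their control transcripts as well as in time, and a biological difference between 4 h and 12 h of EGF stays open and untested against that.

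The control probe sets, which no comparison uses, showed the sets of arrays within each time. The BioD control was at least 21080.5 in the replicate 3 pair at 4 h and at most 594.8 elsewhere. The actin 3' to 5' ratio was at least 11.1 on 5 of the 12 h arrays and 1.24 on EGF replicate 3 at 12 h. That array correlated with its own group at a mean r of 0.905 and with the EGF arrays of 4 h at 0.894, across the tested probe sets.

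For replicate 3 of EGF at 12 h, an EGF culture of 4 h under a 12 h name is argued against by 110 probe sets that changed at least 4-fold at 12 h in the other replicates and not at 4 h. Their signed median against the 4 h controls was 1.73 in replicate 3 (quartiles 0.62 to 2.63, 88.2% with the same sign) and 0.18 in the EGF arrays of 4 h. A control culture under an EGF name is argued against by 3036 probe sets changed alike at both times, with a signed median of 0.83 (quartiles 0.41 to 1.44). Another labelling reaction than that of the other 12 h arrays may account for its place, since its difference from replicates 1 and 2 correlated at r = 0.651 with that of the 4 h from the 12 h controls. No biological explanation was tested for it.

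Between the 12 h and 4 h controls, 8458 probe sets differed, and the highest count of the other splits was 0 with limma, where 1 of the 10 splits, the real one, gave as many, too few splits for a share under 0.05. For the number of lists between the controls, 3 of 10 splits gave at least the real 10, and the highest other gave 11. With an estimated correlation the real number was 6 and the highest other 0. The other splits mix controls of both times in each group, so a difference between the controls widens their spread. Their counts are no measure of chance alone. Another labelling reaction on the 12 h controls may account for a part, since 83.5% of these probe sets had the same sign in EGF replicates 1 and 2 minus replicate 3 at 12 h. RNA degraded before the transcripts were added is argued against as the only source of the skew by the added Thr transcript. Its lowest 3' to 5' ratio on the skewed arrays was 8.90 times the highest at 4 h. Whether the RNA of the cells was degraded as well cannot be told from an added transcript. Time in culture was not tested and stays open.

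At 4 h and at 12 h, 1 of 10 splits gave as many probe sets as the real 5186 and 6730, with 0 by limma in the highest other split, and at 4 h also 1 of the 4 splits that part every pair, with 0 in the other 3. For the number of lists, 1 of 10 splits at each time gave as many as the real 12 and 11, and the highest others were 9 and 8. With an estimated correlation the real numbers were 5 and 5 and the highest others 0 and 0. These splits are too few for a share under 0.05. The others also mix EGF and control arrays in each group, so an effect of EGF widens their spread. Their counts are therefore no measure of what chance alone would give.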

How the results depend on the processing

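The fit with the array set as a block and the fit without the replicate 3 pair at 4 h were chosen only after the results were seen, as were the list tests between the controls. Estimating the correlation between genes left 5, 5 and 3 lists called at 4 h, at 12 h and for the difference, and 6 of 10 between the controls, where quantile normalization left 6 too. The correlation of the effects at 4 h and 12 h was 0.446 with no filter and 0.646 with the filter at the 60th percentile. Median centring gave 1509 probe sets lower at 4 h and 562 with a higher difference. Array weights gave 3191 higher and 5220 lower at 4 h, and 2625 and 2487 for the difference. One probe set per gene gave 1798 higher at 12 h and 4745 between the controls, with fewer probe sets tested. The array set block gave 4960 lower at 4 h and 2168 and 1924 for the difference. At 4 h EGF and control are balanced within each set, so the block leaves the fold changes as they were and acts through the spread. Without EGF replicate 3 at 12 h, which enters that spread, 4181 were lower at 4 h, and the median SE went from 0.230 to 0.192. The cause of the other changes was not tested. Leaving out each array in turn gave 647 to 1501 higher and 757 to 1488 lower differences. The low counts came without control replicate 2 at 4 h (647), EGF replicate 2 at 4 h (668) and control replicate 1 at 12 h (666 and 757), and the high ones without EGF replicate 3 (1501) and replicate 1 (1488) at 12 h. The glycolysis list lost its difference in 11 of 26 alternatives.

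Other counts stayed within 1.5 times when each array was left out: 1631 to 2697 higher and 2233 to 4181 lower at 4 h, 2238 to 3133 and 3052 to 4113 at 12 h, and 6694 to 9869 between controls. No list or named gene turned its direction where it was called. Some that were not called did, as the difference tests of integrins and of endothelial markers, which went from up to down with the array set block (adjusted p = 0.988 and 0.887, ranges over alternatives 0.539 to 0.988 and 0.748 to 0.977). Median centring moved the share of higher calls from 40.8% to 63.8% at 4 h and from 42.3% to 50.2% at 12 h. It moved the median log2 fold change of all probe sets at 4 h from -0.15 to 0.05. With the array set block and an estimated correlation together, 5 list calls at 4 h and 12 h and 3 for the difference that held with the estimated correlation were lost. Of the lists, 2589 comparisons with an alternative stayed on the same side of the threshold, 49 passed newly and 50 no longer passed, and of the named genes 5818, 23 and 70. Where an alternative leaves 2 arrays in a group, the spread is pooled over the groups. For dim genes, signal over background limits what can be seen.

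The replicate block gave 2144 higher and 3076 lower at 4 h, 2929 and 3921 at 12 h, and 960 and 1084 for the difference. It changed 4 calls of lists and named genes: cholesterol synthesis passed at 4 h (adjusted p = 0.0368), glycolysis lost its difference (0.05001), Slc4a4 was lost at 4 h (0.0573) and Stmn3 passed at 12 h (0.0333). It changed no other call. Over their alternatives, these 4 ranged from 0.0199 to 0.293, 0.0170 to 0.278, 0.00319 to 0.509 and 0.0264 to 0.350. At 12 h the arrays with the same number correlated at 0.0826, -0.111 and -0.103 after the group means were taken out.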

Other observations

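The 3 lists tested here were drawn up after the data were seen, with the genes named in the comparisons left out, and each test was fixed before it was run.

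FoxO transcription factors are held out of the nucleus by signalling through Akt, which EGF can start. Of 21 measured FoxO targets, 13 were lower and 1 higher with EGF at 4 h. In limma's camera test p was 5.80e-05, and 1.74e-04 adjusted over the lists. Pik3ip1 (-3.16), Klhl24 (-2.27) and Bcl2l11 (-1.99) were lower by their log2 fold changes, and Trib1 (2.22) was higher. With an estimated correlation p was 0.0336 and adjusted 0.101, which does not pass, and under median centring 11 were lower and 1 higher. At 12 h, 13 were lower and 3 higher (p = 0.00988, adjusted 0.0296, and 0.139 unadjusted with an estimated correlation). Less FoxO activity under EGF may account for the falls, as a hypothesis found and tested on the same arrays.

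NRF2 drives genes of the response to oxidants. Of 18 measured NRF2 targets, 8 were higher and 4 lower with EGF at 12 h (camera p = 0.0645, and 0.124 with an estimated correlation), with Slc7a11 at 2.58 and Gclc at -1.01. Of 18 genes listed as BMP and SMAD targets, 7 were lower and 3 higher at 4 h (p = 0.252, and 0.319 with an estimated correlation). Smad9 (-2.82) and Id3 (-1.74) were among the lower. The 3 higher were Grem1, an antagonist of BMP, at 3.62, Fst at 2.68 and Smurf1 at 1.01. With an antagonist in the list, a test of a shared direction may miss a fall in signalling. The bound written in advance, a p at or above 0.05, was too strict to count against either hypothesis, since a p that misses a threshold does not exclude a smaller shift, so more NRF2 activity and less BMP signalling stay open.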
